A study of Rattus norvegicus with 3 samples.

How the data were processed

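RNA abundance in the vestibular nuclei, the brainstem cell groups that receive the balance signals of the inner ear, was measured on 3 Agilent rat whole-genome arrays in 1 colour. Per the labels, the animals were adult male Sprague-Dawley rats of 200 to 250 g. The arrays held a control, the nuclei on the operated side 1 day after removal of the left labyrinth (the balance organ), and the same nuclei 7 days after it. Each group had 1 array. Per the labels' protocols, the nuclei of 3 rats were used per group because the nuclei of a single rat gave too little RNA, so each array appears to carry pooled RNA. The control is labelled as sham-operated in the sample labels and in the design, while the protocol text calls the control animals normal, and the side taken from controls is not given in the sources used here. The control is called sham below.

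Per the labels, 1 µg of total RNA was labelled with Cy3 during amplification. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1, and all 3 lay on 1 slide, at positions 4 (sham), 3 (day 1) and 2 (day 7), so slide cannot differ between groups while position cannot be told apart from group. The deposited scanner files give, per spot, a processed intensity on a linear scale after background subtraction by the scanner software, and they were not scaled between arrays. Other columns of the deposited files are flags per spot for signal well above background, saturation and outliers. Each file holds 45018 spots, of which 43379 are not controls and belong to 41012 probes. On 10 spots lie 263 probes, and 40749 lie on 1 spot. The authors' series table holds 34687 of these probes. Its values equalled the processed intensity within 0.1 percent for 99.7% of the values on each array, so it is linear, not centred and not scaled between arrays, with column medians of 1596 (sham), 1544 (day 1) and 1688 (day 7). How its probes were chosen is not given in the sources used here, although all 34604 probes that were well above background on at least 1 array are among them.

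The values used here are log2 of the processed intensity minus the array's own 75th percentile of all non-control spots, which was 5692 (sham), 5242 (day 1) and 5676 (day 7). Spots with an outlier flag (163, 224 and 193 in that order) were left out, and the spots of a probe were averaged. Spots well above background made up 81.3% (sham), 77.3% (day 1) and 76.9% (day 7), and the spread of the negative controls was 42.6, 74.5 and 79.6 intensity units, so the dim end was measured less well on both arrays after surgery. Saturated spots numbered 963, 804 and 842. Probes were named through their RefSeq accession in a table of the GRCr8 assembly. It matched 10768 of the 41012 probes, which gave 8899 genes. The other 30244 probes, among them 8830 with Ensembl transcript names, stayed unnamed, and no coordinates are given because the array design uses an older genome build. A gene was represented by its probe with the highest mean over the 3 arrays. It counted as measured in a comparison when that probe was well above background and not saturated on both arrays. This held for 6292 genes at day 1 against sham, 6261 at day 7 against sham and 6142 at day 7 against day 1, and saturation left out 127, 126 and 116 genes.

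With 1 array per group there is no test of conditions, and no p-value is given. A difference is a log2 fold between 2 arrays, and genes were counted at a fixed size of 2-fold. A gene well above background on 1 array, with no probe well above background on the other, has only a bound, given as "at least N-fold". The bound sets the bright value against the higher of the dim probe's own value and the lowest signal that was well above background on that array. For 41 gene lists fixed before the data were examined, the median log2 fold of the measured members was placed among 10000 random lists of the same size, matched on mean level in 20 bins. A median below the 2.5th or above the 97.5th percentile is called outside the range of random lists. This describes these 3 arrays only. About 2.05 of 41 lists would lie outside by chance if the genes of a list varied independently, as in the random lists. Genes of a real list may vary together, and more lists could then lie outside without an effect of surgery.

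Genes were named by a rule fixed at the same time. It takes the 10 highest and 10 lowest named genes of each day against sham and the 5 highest and 5 lowest of day 7 against day 1, among genes brighter than the median well-above-background probe on at least 1 of the 2 arrays and without provisional names. It adds up to 3 genes per direction with the largest bound, the 2 to 4 members with the largest fold of each list described, and 20 preset genes of neuronal activity, glia, inhibition and excitation. Some genes that the rule names are not reported here. Genes outside the rule are identified as chosen after their values were seen.

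Alternatives were quantile normalization, scaling by the median of probes well above background on all arrays, cyclic loess, normexp background correction with an offset of 50, the authors' series table without scaling, no filter on dim probes, a filter to brighter probes, the mean of a gene's probes, outlier spots kept, thresholds of 1.5-fold and 3-fold, unmatched random lists, and the mean instead of the median of a list. The normexp alternative was planned on the mean spot signal. It was run on the median spot signal, the raw spot signal used here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and limma 3.58.1. The counting was tested on simulated data with an array noise of 0.3 log2. In the simulation of day 1 against sham over 6292 genes, 83.0% of genes changed by 1.5 log2 and 100.0% of those changed by 3.0 log2 passed the 2-fold size, as did 2.04% of unchanged genes. The noise was a chosen setting and was not estimated from these arrays. These rates therefore check the counting and give no rate of false calls for the real comparisons.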

Results

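The series addresses vestibular compensation, the recovery of balance after loss of the labyrinth on 1 side. RNA of the rat vestibular nuclei was compared between sham-operated controls and the operated side 1 and 7 days after left labyrinthectomy, on 1 array per group with tissue of 3 rats named for each. There were no replicate arrays, so every value below describes a difference between 2 arrays and has no error from animals, dissections or labellings. Within an array, and without spots marked as outliers, the 10 spots of a replicated probe had a median SD of 0.10 (sham), 0.07 (day 1) and 0.08 (day 7) on the log2 scale. Folds of different probes of the same gene differed by more, although the 2 measures are unlike. The spread of spots is within 1 array, while a difference between 2 folds adds up the errors of both probes on both arrays. At day 1 against sham the log2 folds of the 2 brightest probes of 1139 genes differed by a median of 0.34, with a 90th percentile of 1.29. Their folds correlated at 0.20 across genes, and genes are not independent replicates. Of 74 genes at least 2-fold different by the brighter probe, 17 were at least 2-fold different in the same direction by the next. At day 7 against sham the median difference was 0.41 over 1121 genes, and 26 of 89 genes had such a second probe.

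At day 1 against sham, 520 genes were at least 2-fold higher and 275 at least 2-fold lower among 6292 measured. At day 7 against sham, 698 were higher and 359 lower among 6261. At day 7 against day 1, 403 were higher and 327 lower among 6142. At day 1 higher genes outnumbered lower ones among dim and bright genes alike, and at day 7 only among dim ones. In the dimmer part of the genes, 399 were higher and 206 lower at day 1, and 583 were higher and 223 lower at day 7, whereas in the brighter part 121 were higher and 69 lower at day 1, and 115 were higher and 136 lower at day 7. These counts leave out genes with only a bound. Without provisional names, such genes numbered 166 higher and 311 lower at day 1, and 195 higher and 341 lower at day 7. The lowest signal well above background was 66.9 in sham, 109.0 at day 1 and 121.6 at day 7. Dim genes that were lower after surgery could therefore be left out more easily. Among genes measured on both arrays, higher genes made up 65.4% of those past 2-fold at day 1 and 66.0% at day 7. The share at day 7 was 55.1% under cyclic loess, and that at day 1 was 53.7% in the authors' unscaled values. Without scaling, the median log2 fold of all genes was -0.12 at day 1 against sham and 0.15 at day 7 against day 1. For day 7 against day 1 the share of higher genes was then 66.0% instead of 55.2%.

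**Figure D1:**
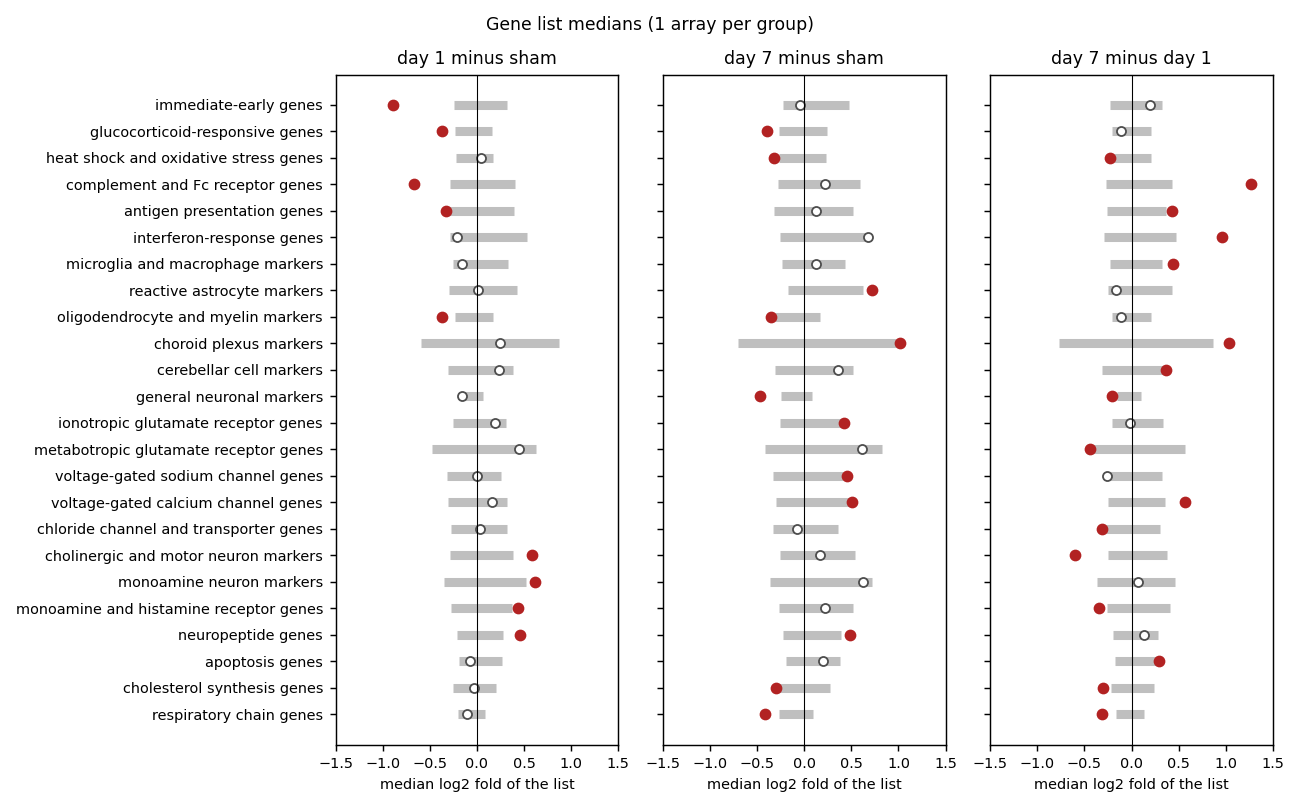
Median log2 fold of the measured members of each gene list (horizontal axis, log2) in the 3 comparisons, for lists outside the range of random lists in at least 1 comparison. Grey bars span the central 95% of 10000 random lists matched on level, filled points lie outside them and open points inside. Immediate-early genes had a median of -0.89 at day 1 against sham, and complement and Fc receptor genes one of 1.26 at day 7 against day 1.

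One day after labyrinthectomy, immediate-early genes, which neurons switch on within minutes of activity, were lower than in sham. Of 16 measured members, 7 were at least 2-fold lower, none was 2-fold higher and 9 were neither. The median log2 fold was -0.89, below all 10000 random lists, and the list stayed outside their range under all 12 alternatives. The lowest were Btg2 (-2.20), Nr4a1 (-2.15), Ccn1 (-2.09) and Ier2 (-1.99). Egr1, a transcription factor measured on 10 spots and chosen after its values were seen, was lower by -1.76 log2, with an error of 0.05 from its spots alone. Fos, the usual marker of recent neuronal activity, was at -1.25. Arc, another activity marker, was not well above background on the day 1 array. Bdnf, a neurotrophin, was at -0.31 by its brighter probe and at 1.03 by the other.

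Complement and Fc receptor genes were low on the day 1 array too. Of 15 complement and Fc receptor genes, 4 were at least 2-fold lower, 11 were neither, and the median of -0.67 lay below all random lists. C3, the central complement protein, was at -2.84, and the antibody receptors Fcgr3a, Fcgr2b and Fcgr2a were at -2.10, -1.69 and -1.62. Antigen presentation genes were mixed, with 3 of 13 higher and 3 lower. The invariant chain Cd74 (-3.19) and RT1-Da (-1.57) were lower, while RT1-S3 (2.32) and RT1-A2 (1.45, with 0.56 for another probe) were higher. The others past 2-fold, chosen after their values were seen, were Psmb9 (-1.04) and RT1-Db1 (1.03). The median of this list was -0.33 (percentile 1.74), and it was inside the range of random lists or reversed under 6 of 12 alternatives. Microglia and macrophage markers had a median of -0.16 (percentile 9.89), inside the range, with 3 of 16 at least 2-fold lower: Tlr2 (-1.80), Cyba (-1.38) and Aif1 (-1.08). Glucocorticoid-responsive genes had a median of -0.37 (percentile 0.06) with none of 14 past 2-fold, and Ddit4 (-0.82) and Per1 (-0.56) were farthest from 0. Myelin genes had a median of -0.38 (percentile 0.03), and Ermn (-1.01) was the only one of 15 past 2-fold. Mal was at 0.98. Mbp, myelin basic protein, was at -0.69 and -0.51 by its 2 probes.

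Neuropeptide genes and cholinergic and motor neuron markers were higher at day 1. Of 23 neuropeptide genes, 7 were at least 2-fold higher, none was 2-fold lower and 16 were neither, with a median of 0.45 (percentile 99.9). The highest were Calcb (2.48), which encodes a calcitonin gene-related peptide, Pdyn (2.04), Grp (2.02) and Nmu (1.62). Of 16 cholinergic and motor neuron markers, 7 were higher and 1 lower, with a median of 0.59 (percentile 99.8). The higher ones included the nicotinic receptor subunit Chrna7 (2.21), the vesicular acetylcholine transporter Slc18a3 (1.82) and the choline transporter Slc5a7 (1.78). Chrna4, another nicotinic subunit chosen after its value was seen, was the member farthest from the list median and lay below it. Calca and Calcb belong to both the neuropeptide and the cholinergic list, so the 2 lists are not independent. Monoamine and histamine receptor genes had a median of 0.43 (percentile 98.8), with 3 of 16 higher and 1 lower, and Drd3 (2.78), Hrh4 (1.51), Htr2b (1.5) and Htr1b (-1.48) were farthest from 0. Monoamine neuron markers had a median of 0.62 (percentile 98.9) over 9 members, with Tph2 (-2.08), Maob (1.56) and Th (1.54) farthest from 0. This list lost its place outside the range or reversed under 4 of 12 alternatives, and the glucocorticoid-responsive (filter to brighter probes), myelin (mean of members) and monoamine and histamine receptor lists (no filter on dim probes) lost theirs under 1 each.

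Most genes of inhibition and excitation were within 2-fold of sham at day 1. GABA genes had a median of 0.03 (percentile 76.1), and glycine genes one of 0.08 (percentile 65.1), both changing sign between scalings. The GABA transporter Slc6a11 was at 1.44, and Gad2, a GABA-synthesizing enzyme, at 1.16. Gad1 was not well above background at day 1 by its brightest probe, and another probe gave 0.71. The vesicular transporter Slc32a1 was at 0.09, the receptor subunit Gabbr1 at 0.08, the glycine receptor Glra1 at 0.95 (-0.05 by another probe) and the glycine transporters Slc6a9 and Slc6a5 at -0.99 and -0.12. The chloride exporter Slc12a5 was at 0.03, and the importer Slc12a2 at -0.75 on 10 spots and 0.05 by another probe. The glutamate receptor subunits Gria2 and Grin1 were at 0.98 and 0.64 and the glutamate transporter Slc17a6 at 0.03. The astrocyte filament Gfap (-0.10), Vim (-0.23) and the growth-cone protein Gap43 (0.07) were close to 0.

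Among genes measured on both arrays that the naming rule admits, the genes with the largest single differences at day 1 did not share a list. Some of them, such as Cd74 and C3, belong to lists described above. Genes with only a bound, given last, were not ranked with them. Tmem98 was higher by 6.41 log2 (84.8-fold), followed by Zfp64 (4.79), the synaptic vesicle protein Sv2c (4.10), Spred2 (4.02), Creld2 (3.84), C4bpb (3.43), the RNA-editing enzyme Adar (3.40), Zdhhc21 (3.37), Inpp5j (3.24) and the astrocyte protein S100b (3.19). The lowest were the calcium channel subunit Cacna1a (-6.76, or 108.1-fold), Cd82 (-4.00), the node-of-Ranvier protein Nfasc (-3.96), Chst1 (-3.26), Cd74 (-3.19), Tifab (-3.19), Nr2c1 (-3.16), C3 (-2.84), Fmo2 (-2.66) and Nhlrc1 (-2.61). S100b was measured on 10 spots and the others on 1 spot each, and no further measured probe of any of these genes was at hand. Pank4 was at least 46.2-fold lower, Fgf11 at least 32.6-fold and Zfp219 at least 13.9-fold. Among genes detected at day 1 and not in sham, the olfactory receptors Or8u9, Or5aq1b and Or52e19 had the largest bounds, at least 14.0-fold, 11.7-fold and 11.2-fold higher.

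At 7 days after labyrinthectomy, general neuronal markers were lower than in sham. Of 18 measured, 3 were at least 2-fold lower, none was higher and 15 were neither. The median was -0.47, below all random lists, and stayed outside their range under all 12 alternatives. All 3 were neurofilament subunits, the structural proteins of large axons: Nefh (-2.30), Nefl (-1.61) and Nefm (-1.17). Respiratory chain genes had a median of -0.41, also below all random lists, with Ndufs4 (-1.41), Atp5f1a (-1.33) and Uqcrc2 (-1.06) as the 3 of 23 past 2-fold, and this list too stayed outside the range under all 12 alternatives. Myelin genes had a median of -0.35 (percentile 0.98), with Mbp (-1.29, and -0.997 by another probe) and Aspa (-1.20) as the 2 of 14 past 2-fold. Glucocorticoid-responsive genes had a median of -0.40 (percentile 0.21), with Pdk4 (-2.45), Ddit4 (-1.66) and Cdkn1a (-1.42) as the 3 of 14 lower. Heat shock and oxidative stress genes had a median of -0.33 (percentile 1.0). Among these, Hspa1a gave -1.63 and 1.202 by its 2 probes, and Cryab was at -1.38. Cholesterol synthesis genes lay at the edge of the range (median -0.30, percentile 2.48) and were inside it under 7 of 12 alternatives, with Hsd17b7 (-1.57) and Fdft1 (-1.21) lowest. The glucocorticoid-responsive and heat shock calls were lost with the filter to brighter probes, and the myelin call with the mean of members.

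Reactive astrocyte markers were higher at day 7. Of 18 measured, 5 were at least 2-fold higher, 2 lower and 11 neither, with a median of 0.72 (percentile 99.2). The call was lost under cyclic loess, under the filter to brighter probes and with the mean of members. The adhesion receptor Cd44 (1.90), the cytokine receptor Osmr (1.88) and Steap4 (1.84) were high, and Vim, an intermediate filament of reactive astrocytes, was at 1.57. Fgf2 gave -2.47 by its brighter probe and 1.75 by the other. Gfap was at -0.26 on 10 spots. Choroid plexus markers, which report epithelium of the nearby brain ventricle, had a median of 1.01 over 4 members (percentile 97.9), with Sostdc1 (1.86) and Folr1 (1.72) higher and Ttr at -0.10, and they were inside the range under 3 of 11 alternatives. Complement and Fc receptor genes had a median of 0.22 (percentile 71.3), with C1qc at 3.31 and 1.03 by 2 probes and C4a at 1.43. Interferon-response genes had a median of 0.68 (percentile 97.4), inside the range, and Rsad2 (1.03) was the only one of 11 past 2-fold. Aif1 was at -0.15.

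Neuropeptide genes were higher at day 7 as well, with 7 of 21 at least 2-fold higher, 4 lower, and a median of 0.49 (percentile 99.2). Cck (2.87), Grp (2.16) and Gal (2.06) were high, and Calcb (-2.38) was low. Of 18 ionotropic glutamate receptor genes, 5 were higher and none lower, with a median of 0.42 (percentile 97.7). They were led by Cacng8 (2.39) and Gria2, the AMPA receptor subunit that limits calcium entry, which was at 1.77 on 10 spots and 1.63 by a second probe. Voltage-gated calcium channel genes had a median of 0.51 (percentile 98.2), with Cacna1i (1.89) and Cacna2d1 (1.62) higher and Cacna1a (-6.70) lower. Sodium channel genes had a median of 0.46 (percentile 98.3), with Scn8a at -1.46 and Scn4a at 1.22. Each of these 3 channel and receptor lists was inside the range, or reversed, under 4 of 12 alternatives. Cholinergic and motor neuron markers were inside the range (median 0.16, percentile 63.5), with Calcb, Slc18a3 (-1.66) and Slc5a7 (-1.43) lower and Isl2 (1.67) higher. Immediate-early genes were also inside it (median -0.04, percentile 20.3, changing sign between scalings). Of 18 measured, 5 were at least 2-fold lower and 2 at least 2-fold higher. Egr2 (2.86) was high, Btg2 (-2.16) and Ccn1 (-2.11, and -0.02 by another probe) were low, and Fos was at -0.12. Arc was at 0.83 on 10 spots and Bdnf at 0.82 and 2.27 by 2 probes.

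At day 7 the glycine transporter Slc6a5, a marker of glycinergic neurons, was 38.3-fold lower (-5.26), and the glycine receptor subunits Glrb (-1.59) and Glra1 (-1.53) were lower. The other 6 of 9 glycine genes were within 2-fold, and the median of -0.02 (percentile 39.3) changed sign between scalings. GABA genes had a median of 0.06 (percentile 66.2), which also changed sign, with 3 of 21 higher and 2 lower. Gad1 gave 3.39 and 1.59 by 2 probes, Gabra4 was at 2.00 and Gad2 at 1.30. Slc32a1 was at -0.02 and Gabbr1 at 0.44. Slc12a2 was at -1.27 (-0.48 by another probe), and Slc12a5 at -0.01. Grin1 (0.45), Slc17a6 (0.18) and Gap43 (0.47) were within 2-fold.

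Genes at day 7 were ranked among those measured on both arrays that the naming rule admits. Genes with only a bound, given last, were not ranked with them. The highest ranked genes were the muscle troponins Tnni3 (6.25) and Tnnt1 (3.95), the keratin Krt8 (5.85), the activin receptor Acvr1b (5.00), Dennd11 (4.61), Creld2 (4.06), Dmtf1 (4.03), Ubxn11 (3.84), the interferon gamma receptor Ifngr1 (3.80) and the olfactory receptor Or13a18b (3.65). The lowest ranked genes were Cacna1a (-6.70), Slc6a5 (-5.26), the pancreatic elastase Cela2a (-4.82), Cyp4a2 (-4.73), the olfactory receptor Or52z1 (-4.47), Nfasc (-4.42), Ap1m1 (-4.17), the sperm glycolytic enzyme Gapdhs (-4.15), Sec14l2 (-4.12) and Slc13a2 (-4.10). Each was measured on 1 spot, and the single further measured probe among them, for Slc13a2, gave 1.28. Hoxa2, a hindbrain patterning gene, was at least 69.5-fold lower, Pank4 at least 44.8-fold and Fgf11 at least 31.7-fold. The 4 measured members of the hindbrain position list were all above 0 at day 7. Their median of 0.59 (percentile 85.5) was inside the range of random lists. Or4s2, Capn3 and Krt26 were at least 48.1-fold, 27.9-fold and 25.1-fold higher.

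**Figure D2:**
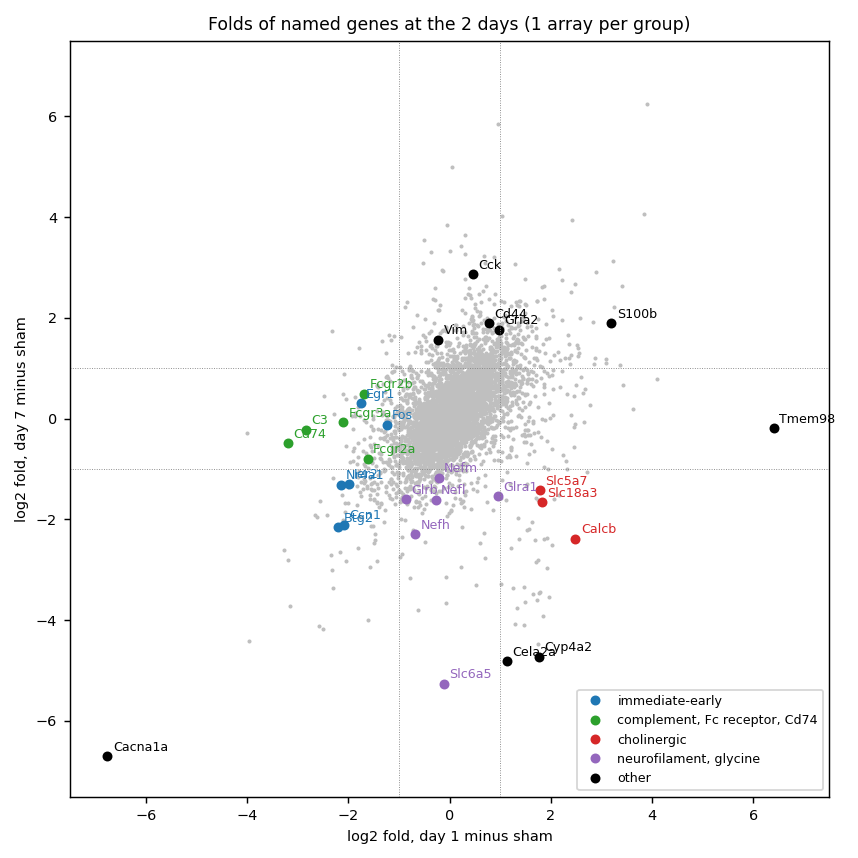
Log2 fold at day 1 minus sham (horizontal axis) and at day 7 minus sham (vertical axis) for each named gene measured on all 3 arrays, with selected genes coloured by group and dotted lines at 2-fold. Btg2 and Ccn1 lie below -2 on both axes, C3 and Cd74 are low at day 1 only, and Calcb, Slc18a3 and Slc5a7 lie at lower right, high at day 1 and low at day 7.

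Between the days, complement, Fc receptor and interferon-response genes were higher at day 7 than at day 1. Of 15 complement and Fc receptor genes, 8 were at least 2-fold higher and none was lower, with a median of 1.26 above all random lists. They included C1qc (3.68, and 0.52 by another probe), C3 (2.63), Fcgr2b (2.18) and Fcgr3a (2.03). Interferon-response genes had a median of 0.96 (percentile 99.99), and all 10 were above 0, led by Ifit2 (1.90), Irf9 (1.49) and Irf1 (1.05). Microglia and macrophage markers had a median of 0.44 (percentile 99.6), with 4 of 17 higher, among them Tlr2 (2.04), Lgals3 (1.29) and Csf1r (1.16). Antigen presentation genes had a median of 0.43 (percentile 98.9), with Cd74 at 2.70 and RT1-S3 at -3.32. The values of C3, Fcgr3a and Cd74 at day 7, chosen after they were seen, were within 2-fold of sham, at -0.22, -0.075 and -0.49. Apoptosis genes had a median of 0.29 (percentile 98.1), with Birc3 at -2.63 and Casp1 at 1.45. Voltage-gated calcium channel genes were all above 0, with a median of 0.57 (percentile 99.9), led by Cacng3 (1.30) and Cacna2d1 (1.14). Vim was at 1.79, Fos at 1.13, Bdnf at 1.13 and 1.25 by 2 probes, and Aif1 at 0.94.

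Cholinergic and motor neuron markers were lower at day 7 than at day 1, with 5 of 16 at least 2-fold lower, none higher, and a median of -0.60 (percentile 0.02). Calcb (-4.87), Slc18a3 (-3.47), Slc5a7 (-3.21) and Isl1 (-1.34) were lowest, and without the lowest 3 the median was 0.01. Those 3 were among 131 probes at least 2-fold higher at day 1 and at least 2-fold lower at day 7 than sham, most of them for unrelated or unnamed genes. Respiratory chain genes had a median of -0.31 (percentile 0.02) with none of 24 past 2-fold and Ndufs4 at -0.72 and Cox5a at -0.68. Neuronal markers had a median of -0.20 (percentile 0.60), with Nefh (-1.62), Nefl (-1.33) and Tubb3 (-1.18) lower. Cholesterol synthesis genes had a median of -0.30 (percentile 0.48), with Fdft1 at -2.25 and Srebf2 at 1.06. Monoamine and histamine receptor genes had a median of -0.35 (percentile 0.72), with Drd3 (-2.50) and Htr1d (-2.04) lowest. Heat shock genes (-0.23, percentile 1.13; Hmox1 -1.78, Gclc 1.02), chloride channel genes (-0.32, percentile 1.37; Clic2 -1.73, Slc4a3 -0.75) and metabotropic glutamate receptor genes (-0.45, percentile 2.36; Grm6 -1.11, Grm4 -0.74) were also outside the range. Choroid plexus markers (1.04, percentile 98.9; Sostdc1 1.76, Ttr 1.11) and cerebellar cell markers (0.36, percentile 98.0; Neurod2 -3.60, Ppp1r17 1.41) were outside it on the high side. Calls were lost or reversed under 5 of 12 alternatives for metabotropic glutamate receptor genes, 4 for monoamine and histamine receptor genes and for cerebellar markers, and 3 for neuronal markers and chloride channel genes. They were lost under 2 of 12 for antigen presentation and apoptosis genes, and 1 of 12 for interferon-response, respiratory chain, cholesterol synthesis and heat shock genes. For choroid plexus markers the call was lost under 1 of 11. Among genes measured on both arrays that the naming rule admits, Acvr1b (4.95), Krt8 (4.89), Cd151 (4.08), Pak2 (4.06) and Ubxn11 (3.88) were highest. Tmem98 (-6.60), Cyp4a2 (-6.49), Or52z1 (-6.21), Cela2a (-5.94) and Or2av9 (-5.75) were lowest among them. Genes with only a bound were not ranked with these. Zfp219, Or4s2 and Ifngr1 were at least 39.7-fold, 27.2-fold and 24.0-fold higher, and Hoxa2, Srms and Tpsb2 at least 69.9-fold, 38.6-fold and 34.9-fold lower. Slc6a5 was at -5.15 and Glra1 at -2.49, while Gria2 (0.79), Mbp (-0.60), Gfap (-0.17), Gad2 (0.14), Slc32a1 (-0.10), Slc12a5 (-0.04), Slc12a2 (-0.51), Slc17a6 (0.16), Grin1 (-0.19), Gabbr1 (0.36) and Gap43 (0.40) were within 2-fold.

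Among 6047 genes measured on all 3 arrays, 182 were at least 2-fold higher at both days and 102 at least 2-fold lower at both. Independent lists of the same sizes would share 48.5 and 14.8 genes. Arrays simulated without any change, which share the control array as the real ones do, gave means of 182.9 (151 to 209) and 179.9 (153 to 216). The simulation took the whole spread between the real arrays as noise, so a large overlap was built into it. The log2 folds at the 2 days correlated at 0.45 across genes, against 0.50 in the simulation, with a covariance of 0.25 against 0.28. The count of genes lower at both days was below every simulated one, so this simulation does not describe the lower side. It gave nearly the same mean in both directions, unlike the real arrays. The near match on the higher side therefore does not show that the shared control accounts for the overlap there. Part of the overlap may come from the single control array, which cannot be split, and how large that part is cannot be told from these arrays. Opposite changes were uneven: 47 genes were higher at day 1 and lower at day 7, and 9 were lower at day 1 and higher at day 7. Independent lists of the same sizes would share 26.2 and 27.4 genes. The simulation gave means of 5.92 (1 to 11) and 6.51 (1 to 16). Both counts involve lower genes, which the simulation does not describe, so it gives no measure for them.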

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

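In this part the tests of scaling, of probes with a shared profile and of random lists trimmed like the real one were chosen only after the result was seen. Of 47 genes at least 2-fold higher than sham at day 1 and at least 2-fold lower at day 7, 11 were among those picked by the rule for naming genes, and they stood out as opposite between the days. With 1 array per group the difference between the days was not tested. They were Calcb (2.48 at day 1 and -2.38 at day 7, log2), Slc18a3 (1.82 and -1.66), Slc5a7 (1.78 and -1.43), Nrtn (1.57 and -2.19), Vegfa (1.79 and -3.44), Fdft1 (1.04 and -1.21), RT1-S3 (2.32 and -1.002), Cela2a (1.13 and -4.82), Cyp4a2 (1.76 and -4.73), Or52z1 (1.74 and -4.47) and Slc13a2 (1.47 and -4.10). A second probe of Vegfa gave 0.25 and -0.63, and that of Slc13a2 gave 1.28 at day 7.

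Calcb, Slc18a3 and Slc5a7 mark cholinergic and motor neurons, and their list was high at day 1 and low at day 7 against day 1. A trend with intensity or scaling is argued against, since the highest list median at day 7 against day 1 over the other 5 scalings was -0.46. Unrelated errors of single probes stay open: without its lowest 3 members the list lay at percentile 38.4 of untrimmed random lists, the test written first, and at percentile 14.2 of random lists that also lost theirs, a fairer version made after the first had been seen. A signal shared with probes for unrelated genes stays open too, since 131 probes had this profile and 33 its mirror image, a ratio of 3.97. The 52 named genes among the 131 included 8 olfactory receptors. The share of olfactory receptors among all measured genes was not counted, so the 8 cannot be read as an excess. Different amounts of tissue from neighbouring motor nuclei may also contribute. The 6 measured of 11 further motor neuron markers had a median of -1.14 at day 7 against day 1 (percentile 0.02), and all 6 were below 0. The comparisons with sham do not place the difference. By their median the further markers were low at day 7 (-0.57, percentile 1.3), while the cholinergic list was not (0.16, percentile 63.5). Members of the further list disagreed at day 7: Anxa4 (-1.66) and Sncg (-1.27) were at least 2-fold lower and Slc10a4 (1.295) at least 2-fold higher. At day 1 the further markers were inside the range of random lists (0.27, percentile 85.6), with 2 of 7 at least 2-fold higher and 2 at least 2-fold lower. A change in these neurons after surgery was not tested.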

How the results depend on the processing

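With 1 array per group, no array could be left out. No paired analysis was possible because no result comes from a test of replicates. The count of every probe with or without a gene name, other probes of a gene, and lists without their most extreme member were added after the data were seen. Under quantile normalization, median scaling, cyclic loess, the authors' unscaled values, the mean of a gene's probes and outlier spots kept, each count of genes past 2-fold was within 1.5 times the value reported, and cyclic loess shared 425 of the 520 higher and 273 of the 275 lower genes at day 1. Under normexp background every count was lower, with 406 higher and 200 lower at day 1 and 524 higher and 296 lower at day 7. There, 110 genes instead of 182 were higher at both days, and the cause was not tested. Without the filter on dim probes, which tests more genes, 933 were higher and 636 lower at day 1, 1265 and 718 at day 7, 868 and 703 at day 7 against day 1, and 403 higher and 305 lower at both days. With the filter to brighter probes, which tests fewer, these were 173 and 116, 195 and 192, 149 and 163, and 29 and 55. Over every probe with or without a gene name they were 2280 and 1150, 3204 and 1687, 1849 and 1624, and 941 and 423. By construction, 1.5-fold gave 1152 and 736, 1483 and 822, and 974 and 757, and 3-fold gave 168 and 87, 218 and 140, and 143 and 159. Of the lists outside the range of random lists, 4 medians turned sign: antigen presentation at day 1 without the filter on dim probes (0.15), monoamine neuron markers at day 1 (-0.19) and sodium channel genes at day 7 (-0.57) with the filter to brighter probes, and cerebellar markers at day 7 against day 1 with the mean of members (-0.022). The cause was not tested. The alternatives fixed beforehand turned no named gene past 2-fold, while another probe gave the opposite sign for Fgf2 (0.12 at day 1, 1.75 at day 7), Hspa1a (0.32 and 1.202), Slc13a2 at day 7 (1.28) and Vamp1 at day 7 against day 1 (0.002). Of the list medians under the alternatives fixed beforehand, 60 lost and 33 gained a place outside the range and 1241 kept their side. The lowest signal well above background was 66.9 in sham, 109.0 at day 1 and 121.6 at day 7, which limits what could be measured among dim genes after surgery.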

Other observations

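In this part the tests of whole transcripts, of mean brightness, of single spots with outlier spots kept, of scaling, of trimmed random lists and of the sham sample were chosen only after the result was seen. Some gene groups inside the range of random lists held members with large differences. Among ependymal and ciliated cell markers at day 7 against sham, Rsph1 (2.94), Drc12 (2.28, and 2.95 by another probe) and Foxj1 (1.77), the master regulator of motile cilia, were higher, 3 of 8 measured, while Tekt1 (-0.88) was not. Meningeal and fibroblast markers at day 7 had Fmod (2.27), Aldh1a2 (1.76) and Pcolce (1.07) higher, 3 of 13, at percentile 88.7. Astrocyte markers had a median of -0.04 at day 7 that changed sign between scalings, with S100b (1.89) and the water channel Aqp4 (1.25) higher, 2 of 17.

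Synaptic vesicle and release genes went both ways at day 7 against sham, with 4 of 25 higher and 3 lower and a median of -0.04 that changed sign between scalings. The scaffold Dlg4 was at 2.45 and 3.89 by 2 probes, Syt11 at -2.06 and Rab3a at -1.35. Axon growth and nerve injury genes had a median of 0.32 (percentile 93.2), with Gal (2.06), Csrp3 (1.94) and Rtn4 (-1.68) farthest from 0. Potassium channel genes had a median of 0.16 (percentile 85.0), with Kcnj4 (1.90), Kcnab2 (-1.497) and Kcnk3 (1.41). Growth factor genes had 2 of 24 higher and 4 lower: Vegfa (-3.44, and -0.63 by another probe), Fgf2 (-2.47, and 1.75 by another probe), Nrtn (-2.19) and the low-affinity neurotrophin receptor Ngfr (-1.53). Cell division genes had a median of 0.54 (percentile 91.0) over 10 members, with Aurka at 1.43 and Cdc20 at 0.90. Ribosomal protein genes had none of 35 past 2-fold at either day.

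Many of the largest differences rested on 1 probe. A change of the whole transcript stays open: where the brighter probe of a gene moved by at least 2 log2 against sham, the next probe moved by at least 1 log2 the same way in 0 of 5 cases at day 1 and 9 of 19 at day 7, a share of 0.375 over both days from few cases. Damage or misreading of single spots may account for a small part, but the tests leave it undecided. With spots marked as outliers kept, 7 of 6226 spots of replicated probes lay 2 log2 or more from their probe's median. That share, times 2 for the 2 arrays of a comparison, was 0.0988 of the rate of single-spot folds of that size. The ratio was 0.136 with the count of spots raised by its square root. The ratio of 0.0 in the test written first decides nothing because those spots had been left out. Large folds were not particular to single-spot probes. Folds of 2 log2 or more were 12 of 394 among 10-spot probes and 1335 of 59060 among single-spot probes. At 1 log2 the shares were 15.0% and 11.5% at day 1, and 20.1% and 16.5% at day 7. Signal close to background on 1 of the arrays may account for part: the test written first gave a rate 0.0855 times as high among probes bright on both arrays as among the rest, but it decides nothing because a large fold itself makes a probe dim on 1 array, and a version by mean brightness, made after that was seen, gave 0.244 and left it undecided. Of 149 probes at least 8-fold lower at day 7 than at day 1, 128 were at least 2-fold higher at day 1 than sham. Of 72 at least 8-fold higher, 20 were at least 2-fold lower at day 1. The day 1 array enters both comparisons, so probes picked in this way tend to lie far from sham at day 1. How much of either share comes from that was not estimated. Whether a shared hybridizing RNA or transcript variants lie behind the uneven shares was not tested.

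Immediate-early genes were low at day 1. A trend with intensity or scaling is argued against, since their highest median over the other 5 scalings was -0.77. Unrelated errors of single probes are argued against too, because without its lowest 3 members the list lay at percentile 0.0 of untrimmed random lists, the test written first, and at percentile 0.0 of random lists that also lost theirs. High levels in the sham sample alone stay open: the median of the 16 members was higher by 0.78 at day 7 than at day 1, barely more than the SD of 0.77 of their differences, while the median of those differences was only 0.195. Of the 16, 9 were lower than sham at day 7. Among the 18 measured at day 7 against sham, 5 were at least 2-fold lower and 2 at least 2-fold higher. Members went apart: Btg2 (-2.16) and Ccn1 (-2.11, but -0.02 by another probe) were as low at day 7 as at day 1, whereas Egr1 (2.06), Atf3 (2.00) and Fos (1.13) were higher at day 7 than at day 1. Differences in handling before tissue collection and an effect of labyrinthectomy on neuronal activity were not tested and stay open.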
